A study of Mus musculus with 23 samples.

How the data were processed

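The samples were CD8+ T cells from mouse spleen, from animals whose Plpp1 gene carries loxP sites (called WT here) or that also carry a Cre recombinase under the Lck promoter (called KO here), and the cells were untreated or given octadecenoic acid (OA) or arachidonic acid (AA), per the labels. Polyadenylated RNA was extracted with TRIzol and made into libraries with a stranded messenger RNA kit, per the labels' protocols. Doses and treatment times are not in the labels. Reads were trimmed with Trimmomatic 0.36 and assigned to genes of GRCm38 with featureCounts of Subread 1.5.1, per the submitters' processing notes. The aligner, the annotation release and the strand and pairing settings of the counting are not given in the sources used here.

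The values used were the raw counts per gene in the deposited table of 49492 genes and 23 libraries. Columns were matched to samples by their names. Replicate 3 of untreated WT and of untreated KO stand at other positions in the table than in the list of samples, so their names and not their positions decided their group. Among counts from 1 to 19, between 66.5% and 70.7% per library were even, a pattern that arises when both mates of a pair are counted. Genes that overlap a neighbour or have an antisense partner, such as Txnrd1 with Eid3, Tpi1 with Spsb2, Cyp51 with Akap9, Acadvl with Dvl2, Aldoa with Fam57b, Plpp1 with Skiv2l2 and Xist with Tsix, could share reads under such counting, so their values are uncertain. Total counts lay between 39265131 and 58878203 per library, and 21884 to 24452 genes had at least 1 count. The 10 most abundant genes took 5.72% to 6.76% of the counts.

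Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total 15, over the 6 groups), which left 18015 genes holding 99.964% of all counts. Scaling factors between libraries were computed by TMM and lay between 0.961 and 1.034. edgeR 4.0.16 in R 4.3.3 fitted a quasi-likelihood model with 1 mean per group to all 23 libraries, with 17 residual degrees of freedom and 17.9 prior degrees of freedom. The common biological coefficient of variation was 4.97%. The 11 comparisons were KO against WT without fatty acid, with AA and with OA, each fatty acid against none in each genotype, AA against OA in each genotype, and the difference of each fatty acid's effect between genotypes. Adjusted p-values are Benjamini-Hochberg values over all tested genes within 1 comparison, with a threshold of 0.05 and no limit on the fold change. Values per gene are CPM scaled by TMM, given as mean ± SD over the libraries of a group. The labels do not state that libraries come from separate animals, so p-values measure the spread between these libraries only.

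Gene lists, 37 in all, covered lipid, redox, T cell state, stress and metabolism genes and the marker genes of cell types, and 36 had the minimum of 3 tested members. They were tested with camera of limma 3.58.1 at its preset correlation of 0.01, which compares the members with all other tested genes, and adjusted over the lists within 1 comparison. Calls were repeated with a correlation estimated from the libraries. Lists can share members, such as Gclc, Txnrd1 and Ftl1 of NRF2 targets and ferroptosis defence, so calls of different lists are not always separate results. Counts of members past the threshold are given over all tested genes and again adjusted over the list alone. The groups, lists, comparisons, tests, alternatives and the rule for named genes were fixed before the data were examined, except those said below to be chosen after results were seen.

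Genes were named by this rule. In every comparison, 21 genes chosen for the study's subject were taken where tested. In the comparisons of KO with WT without fatty acid and of each fatty acid with none, the 6 genes with the largest change in each direction were taken, and 4 in the others. These had an adjusted p under 0.05, a mean log2 CPM of at least 1 and no overlap between the libraries of both groups, and predicted genes, pseudogenes and antigen receptor segments were left out. For differences between effects the lack of overlap was not asked. From each list with a camera adjusted p under 0.05, up to 4 members with the smallest adjusted p in the list's direction were taken. The text names those it has room for. Receptor, sex-linked, repeat-type and mitochondrial transcripts were measured apart from this rule, as shares of counts or plain CPM.

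Alternatives tried were DESeq2 1.42.0, limma-voom with quality weights, RLE and upper quartile factors, no filter, a stricter filter (1 CPM in at least 4 libraries and 10 CPM in at least 1), only the groups compared, the replicate number as a block, each library left out in turn, and fry for the lists. Shared controls were simulated 20 times with unchanged groups, and other splits of the libraries were counted. The procedure was tested on simulated data made from the real means and library sizes, with 50 genes changed per fold size. For KO against WT without fatty acid, it recovered 44% of genes changed 1.2-fold, 72% at 1.5-fold, 86% at 2-fold and 92% at 4-fold, with 4 of 17815 unchanged genes called. For AA against none in WT the shares were 44%, 60%, 78% and 94%, with 9 unchanged genes called. With the difference in the AA effect between genotypes they were 22%, 58%, 72% and 84%, with 3 unchanged genes called. The test of lists called the changed list and 0 of 30 unchanged lists. Genes varied independently in the simulation, so it could not show false calls that arise from correlated members.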

Results

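Polyadenylated RNA was sequenced from CD8+ T cells of mouse spleen in 6 groups that cross genotype with fatty acid. PLPP1 is a membrane lipid phosphatase, and the KO cells came from floxed animals with a Cre recombinase active in T cells, while the WT cells carried the floxed gene without Cre. The study's title concerns PD-1 signalling, ferroptosis (cell death by oxidised membrane lipids) and antitumor activity of T cells. Cells were untreated or given octadecenoic acid (OA), a monounsaturated fatty acid, or arachidonic acid (AA), a polyunsaturated one that is readily oxidised. Each group had 4 libraries except KO with OA, which had 3. Total counts per library ran from 40057517 to 56531567 in untreated WT, 39705882 to 45354545 in WT with OA and 42509559 to 49202127 in WT with AA. In KO they ran from 39265131 to 48088112 untreated, 41999520 to 49363285 with OA and 48288680 to 58878203 with AA.

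Plpp1, the targeted gene on chromosome 13 (GRCm38, 112800894 to 112867881), was near the floor in both genotypes. Untreated WT libraries held 32, 20, 17 and 32 counts of Plpp1 and untreated KO libraries 19, 19, 25 and 21. With OA the counts of Plpp1 were 21, 29, 39 and 23 in WT and 15, 37 and 25 in KO. With AA they were 35, 35, 19 and 19 in WT and 23, 36, 29 and 36 in KO. Untreated, the level was 0.559 ± 0.201 CPM in WT and 0.507 ± 0.0406 CPM in KO (SD, n = 4 each). The log2 difference was -0.12 without fatty acid (edgeR adjusted p = 0.774, 95% confidence interval -0.76 to 0.52), 0.09 with AA (0.841) and -0.19 with OA (0.688). The lower end of the untreated interval is 0.589 of the WT level, so a larger loss of counts over the whole gene lies outside it. The labels do not say which exons the deletion removes, and Plpp1 overlaps Skiv2l2 on the other strand, whose reads it could share. These counts therefore do not check the genotype labels.

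The genotypes separated by antigen receptor and sex-linked transcripts. In all 12 WT libraries, 1 beta chain variable gene, Trbv12-1, made up 84.5 ± 1.16% of the counts of the 35 Trbv genes, against 3.87 ± 0.302% in the 11 KO libraries. Trav14, a family of 9 alpha chain variable genes, made up 79.8 ± 1.26% of the counts of the 128 Trav genes in WT and 11.2 ± 0.502% in KO. The joining segment Traj33 lay at 36.5 ± 2.45 CPM in WT and 1.19 ± 0.150 CPM in KO. Trac, the constant segment of the alpha chain, lay at 261 ± 12.9 and 127 ± 6.61 CPM, and Trdc, that of the delta chain, at 49.4 ± 2.79 and 1.74 ± 0.271 CPM. Xist, the transcript that silences 1 X chromosome in female cells, lay at 859 ± 29.8 CPM in WT and 3.89 ± 0.830 CPM in KO. Ddx3y, a Y chromosome gene, was present in both, at 61.5 ± 2.08 CPM in WT and 100.4 ± 4.26 CPM in KO. Shares above 2% of the Trbv counts belonged to 3 genes in WT and 15 in KO. These differences run with genotype in every library, so no comparison of KO with WT here separates the deletion of Plpp1 from them.

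**Figure D1:**
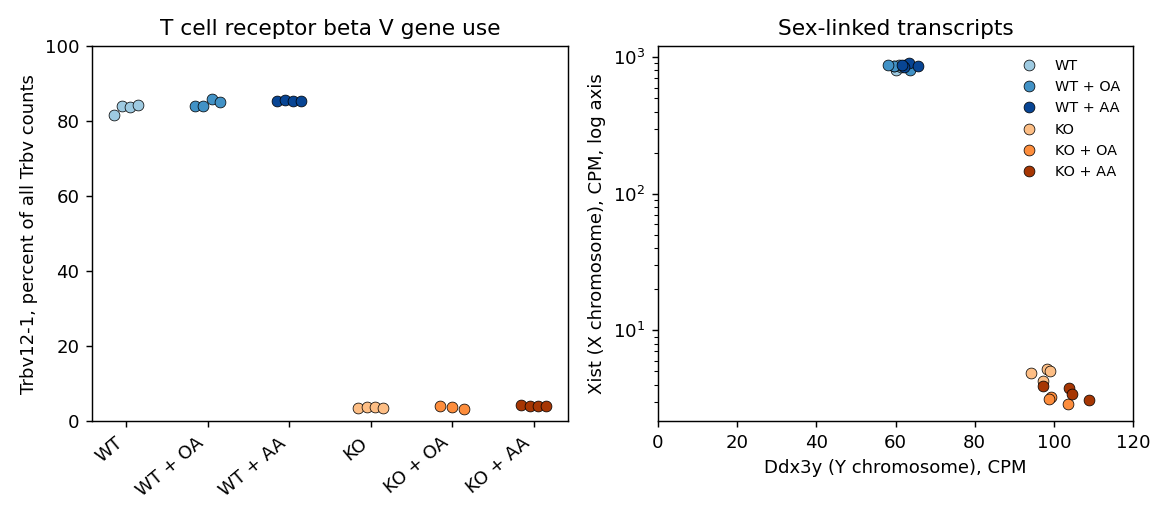
Left, Trbv12-1 as a percent of all Trbv counts per library and group; right, Xist against Ddx3y in plain CPM per library, with Xist on a log axis. Points are libraries, and WT libraries averaged 84.5% Trbv12-1 and 859 CPM Xist against 3.87% and 3.89 CPM in KO.

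The first question was how the genotypes differ without fatty acid. KO T cells had more transcripts of cell cycle, glycolysis and cholesterol synthesis genes and fewer of interferon-response genes than WT T cells. Gzmb, which encodes the cytotoxic protease granzyme B, was 2.13-fold higher in KO (422 ± 11.9 against 198 ± 4.42 CPM, SD, n = 4 each). Tfrc, the transferrin receptor that brings iron into dividing cells, was 1.79-fold higher (265 ± 4.27 against 148 ± 3.43 CPM). Idi1, an enzyme of sterol synthesis, was 2.60-fold higher and Ldha, the lactate dehydrogenase of glycolysis, 1.78-fold higher. Zbp1, an interferon-induced sensor of nucleic acid, was 2.13-fold lower (58.6 ± 1.55 against 124.7 ± 3.27 CPM), and Il7r, the interleukin 7 receptor of naive and memory cells, 1.90-fold lower. Of 18015 genes tested by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4619 were higher and 4356 lower in KO, and 1078 of these 8975 differed at least 2-fold. Their median change was 1.29-fold.

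Among genes the naming rule takes, which leaves out predicted genes and receptor segments, the largest differences between untreated genotypes were losses. Mme, the surface peptidase CD10, fell by 7.57 on the log2 scale, from 28.2 ± 1.22 CPM in WT to 0.143 ± 0.116 CPM in KO (edgeR adjusted p = 1.12e-28). Xist and its antisense partner Tsix fell by 7.41 and 7.11, Magi1, a scaffold of cell junctions, by 5.39, Plch1, a phospholipase C, by 4.39 (20.9-fold) and the olfactory receptor gene Olfr524 by 2.81 on that scale. Higher in KO were Evpl, a junction protein (log2 1.76), Drc1, a ciliary protein (1.71), Arsb, a lysosomal sulfatase (1.70), and Nt5e, the adenosine-producing surface enzyme CD73 (1.59). Cdkn1a, the p53-induced cell cycle inhibitor, rose by 1.58 and Serpine2, a protease inhibitor, by 1.51. The naming rule asked that no library of either group overlap the other group for these genes. Among genes tied to the study's subject, Pdcd1, which encodes PD-1, was 1.19-fold higher in KO (12.8 ± 0.417 against 10.8 ± 0.600 CPM, edgeR adjusted p = 0.00161). Acsl4, which loads polyunsaturated fatty acids into lipids and favours ferroptosis, was 1.12-fold higher (3.70e-04). Gpx4, the glutathione peroxidase that blocks ferroptosis, was 1.12-fold higher (0.00425), a call lost without KO replicate 3 (0.0526). Tcf7, a transcription factor of naive and stem-like T cells, was 1.28-fold lower (2.04e-11), while Slc7a11, the cystine importer, did not pass (0.357 ± 0.242 against 0.624 ± 0.220 CPM, edgeR adjusted p = 0.0545), although it passed without KO replicate 1 (0.0043), without WT replicate 1 (0.0479) or 2 (0.0456), with DESeq2 (0.0373) and with the replicate block (0.0493).

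Gene lists were then tested for untreated KO against WT. All 30 cell cycle genes tested were higher in KO (30 adjusted over the list alone), with a median log2 change of 0.41 and a camera adjusted p of 1.26e-20, led by the ribonucleotide reductase genes Rrm1 and Rrm2 and the replication genes Pcna and Mcm2. Cholesterol synthesis and uptake had 22 of 25 members higher and 1 lower (23 and 1 adjusted over the list alone, camera adjusted p = 1.09e-14). Glycolysis and hypoxia genes had 19 of 26 higher and 2 lower (19 and 2 adjusted over the list alone, 2.16e-10). The integrated stress response, a programme for amino acid shortage that includes Asns and Phgdh, had 18 of 30 higher and 2 lower (18 and 3 adjusted over the list alone, 5.50e-05). Heat shock chaperones had 11 of 15 higher (11 adjusted over the list alone, 1.60e-05). For p53 and apoptosis genes 16 of 21 were higher and 4 lower (16 and 4 adjusted over the list alone, 7.07e-04), and for fatty acid synthesis 12 of 17 were higher and 3 lower (12 and 3 adjusted over the list alone, 0.0175). Type I interferon response genes had 17 of 26 lower and 3 higher (17 and 3 adjusted over the list alone, 2.15e-09), among them Gbp2. Genes of NF-kB and TNF signalling, such as Tnfaip3 and Bcl3, had 13 of 21 lower and 2 higher (13 and 2 adjusted over the list alone, 0.00376). All of these 9 calls held with an estimated correlation.

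A further 6 lists passed camera for untreated KO against WT at the preset correlation and not at the estimated one. Oxidative phosphorylation had 37 of 42 members higher (37 adjusted over the list alone), including Atp5b and Cycs, with adjusted p = 0.0676 with an estimated correlation. For NRF2 targets, the antioxidant genes driven by that transcription factor, 14 of 23 were higher and 2 lower (14 and 3 adjusted over the list alone) with adjusted p = 0.0644 with an estimated correlation. Chaperones of the endoplasmic reticulum had 15 of 21 higher and 2 lower (15 and 2 adjusted over the list alone), with adjusted p = 0.0676 with an estimated correlation. Ribosomal protein genes had 28 of 39 lower and 1 higher (29 and 1 adjusted over the list alone), with adjusted p = 0.468 with an estimated correlation. Naive and memory genes had 11 of 20 lower and 4 higher (11 and 4 adjusted over the list alone), with adjusted p = 0.104 with an estimated correlation. Targets of LXR, the oxysterol receptor, had 7 of 11 lower and 2 higher (7 and 2 adjusted over the list alone), with adjusted p = 0.116 with an estimated correlation, and among them Abca1, a cholesterol exporter, fell by 0.88 on the log2 scale. Lists of ferroptosis defence (camera adjusted p = 0.0848), CD8 effector genes (0.0848) and ferroptosis promotion (0.274) did not pass. Markers of other blood cells did not pass as lists either, with 0.108 for megakaryocytes and platelets, 0.113 for dendritic cells and 0.308 for macrophages and monocytes. Single markers of such cells were still lower in KO, such as the platelet genes Itga2b (3.43 ± 0.382 against 7.24 ± 0.900 CPM, SD, n = 4 each, edgeR adjusted p = 1.41e-10) and Pf4 (log2 -1.74, 1.21e-07). Dendritic cell markers lower in KO were H2-Ab1 (log2 -1.24, 7.20e-14), Cd74 (-0.80, 2.02e-10), H2-Eb1 (-0.99, 5.01e-06) and, near the floor, H2-Aa (-1.46, 3.07e-04). Batf3 was higher (0.0162), while Itgax (0.64), Zbtb46 (0.231), Flt3 (0.0721) and Xcr1 (0.256) did not pass. All these markers were named after their values were seen. Whether the share of other cells differs between genotypes was not tested.

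**Figure D2:**
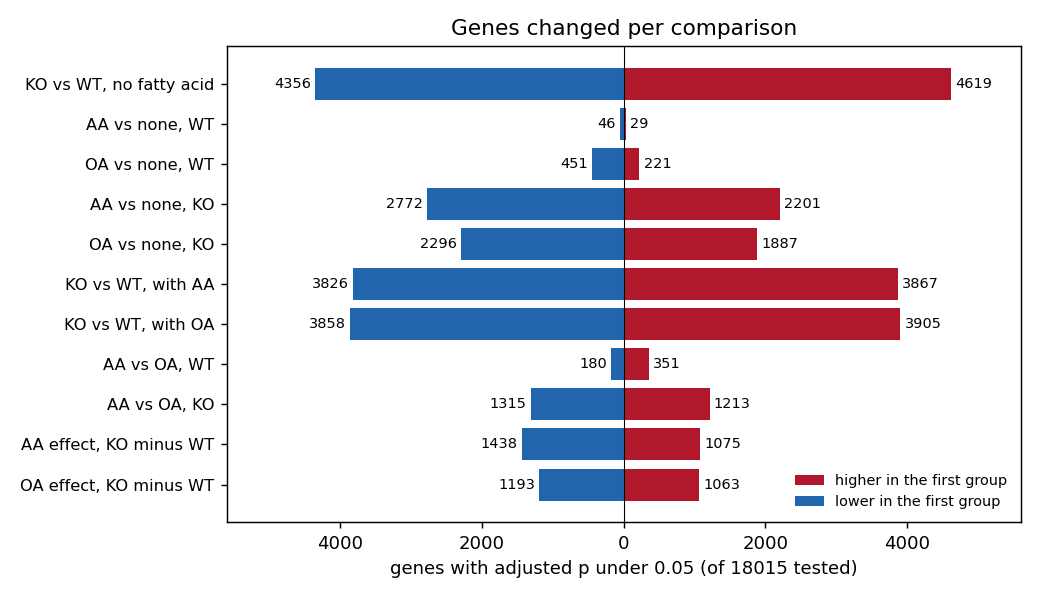
Genes with an edgeR adjusted p under 0.05 per comparison, of 18015 tested; bars to the right count genes higher in the first group and bars to the left genes lower in it. The count ran from 75 for AA against none in WT to 8975 for KO against WT without fatty acid.

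The next question was what AA does in WT T cells. It raised antioxidant genes and lowered sterol and fatty acid synthesis genes. Nqo1, an NRF2-driven quinone reductase, was 3.09-fold higher with AA (3.03 ± 0.638 against 0.974 ± 0.156 CPM, SD, n = 4 each, edgeR adjusted p = 8.03e-09). Txnrd1, the thioredoxin reductase, was 1.48-fold higher (121 ± 3.54 against 82.0 ± 2.73 CPM, 4.10e-14), though its reads may be shared with Eid3, which lies in it and was 1.73-fold higher. Gclc, the enzyme that starts glutathione synthesis, was 1.30-fold higher, Cpt1a, which admits fatty acids to mitochondria for oxidation, 1.26-fold, and Arrdc3, an arrestin-like adaptor, 1.39-fold. Fads2, a desaturase, fell by 0.80 on the log2 scale and Insig1, a sterol-sensing regulator, by 0.48. The test called 29 genes higher and 46 lower with AA in WT, of which 1 differed at least 2-fold. The number rested on the libraries: 48 genes passed without WT replicate 1, and DESeq2 called 137. With upper quartile factors 28.2% of the called genes were higher, against 38.7% with TMM.

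Among the study's genes in WT with AA, neither the ferroptosis genes Gpx4 (40.3 ± 0.569 against 40.5 ± 1.72 CPM) and Acsl4 (69.6 ± 1.28 against 69.0 ± 2.33 CPM) nor the effector gene Gzmb (199.9 ± 2.99 against 198 ± 4.42 CPM) passed the test. Scd1, a desaturase that makes monounsaturated fatty acids, fell by 0.57 on the log2 scale (edgeR adjusted p = 0.0102), a call lost without WT replicate 4 (0.0503), WT with AA replicate 1 (0.0545) or replicate 3 (0.0633). Scd2, its relative, fell by 0.29 (2.28e-07). Cholesterol synthesis and uptake had 8 of 25 members lower (15 adjusted over the list alone), with a median log2 change of -0.17 and a camera adjusted p of 2.10e-40. NRF2 targets had 7 of 23 higher (12 higher and 2 lower adjusted over the list alone, camera adjusted p = 3.88e-27). Fatty acid synthesis had 4 of 17 lower (6 lower and 1 higher adjusted over the list alone, 3.41e-10), LXR targets 2 of 11 lower (4 adjusted over the list alone, 5.10e-05) and type I interferon genes 1 of 26 lower (6 adjusted over the list alone, 2.36e-07), the 1 being the nucleotide kinase gene Cmpk2. These 5 calls held with an estimated correlation. Ferroptosis defence had 4 of 27 members higher and 2 lower (6 and 3 adjusted over the list alone, camera adjusted p = 0.00195), with adjusted p = 0.0797 with an estimated correlation. Fatty acid oxidation had 2 of 28 higher (2 adjusted over the list alone), with adjusted p = 0.222 with an estimated correlation. Ribosomal proteins, oxidative phosphorylation and mitochondrial genome transcripts had medians of -0.05, -0.04 and -0.10, with camera adjusted p of 1.04e-06, 0.00827 and 0.0117. Their calls were lost, with adjusted p = 0.321, 0.417 and 0.409 with an estimated correlation.

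The same question was asked for OA in WT T cells. OA raised fatty acid oxidation genes and lowered fatty acid synthesis genes and naive and memory genes. Cpt1a was 2.27-fold higher (124 ± 2.11 against 54.6 ± 1.84 CPM, SD, n = 4 each, edgeR adjusted p = 1.14e-25) and Plin2, a coat protein of lipid droplets, 2.26-fold higher (21.7 ± 2.16 against 9.64 ± 1.47 CPM, 2.07e-12). The desaturase genes Scd1, Fads2 and Scd2 fell by 1.40, 1.11 and 0.62 on the log2 scale. Other genes moved too: Dtx1, a Notch pathway regulator, rose by 1.06, Gzma, a granzyme, by 0.97, Fosb, an early response gene, by 1.05 and Tgm2, a transglutaminase, by 0.89. Lower were Olfr524 (log2 -1.03), Dntt, the polymerase of receptor rearrangement (-0.95), and Gucy2e, a guanylate cyclase (-0.89). OA changed 672 genes in WT, with 221 higher and 451 lower, and 436 without WT replicate 2. Gzmb was 1.10-fold lower (edgeR adjusted p = 0.00591), and Gpx4, Acsl4 and Pdcd1 did not pass (0.711, 0.312 and 0.893).

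Fatty acid oxidation and PPAR targets had 6 of 28 members higher with OA in WT (7 adjusted over the list alone, camera adjusted p = 3.44e-25), among them Acadvl and Etfdh of the oxidation pathway, whose counts could include a neighbour's reads. Naive and memory genes had 12 of 20 lower (13 lower and 1 higher adjusted over the list alone, 3.09e-20), including Il7r. Fatty acid synthesis had 6 of 17 lower (7 adjusted over the list alone, 1.38e-13) and LXR targets 5 of 11 lower (5 adjusted over the list alone, 4.72e-12), with Abcg1, a sterol exporter, down 1.33-fold. Glycolysis and hypoxia had 7 of 26 higher (10 higher and 1 lower adjusted over the list alone, 3.23e-07), including Bnip3, a hypoxia-induced mitophagy gene. Immediate early genes had 4 of 16 higher (8 adjusted over the list alone, 1.91e-04), and Egr1 among them rose 1.34-fold. NRF2 targets had 5 of 23 higher (7 adjusted over the list alone, 2.31e-04), and dendritic cell markers 2 of 9 lower (4 adjusted over the list alone, 9.58e-04). These 2 markers were Batf3 and Cd74, while Itgax (edgeR adjusted p = 0.164), Zbtb46 (0.387), Flt3 (0.728) and Xcr1 (0.904) did not pass. All 8 lists held with an estimated correlation. Cell cycle genes had 3 of 30 lower (5 adjusted over the list alone, camera adjusted p = 0.00848), with adjusted p = 0.0538 with an estimated correlation. Cholesterol synthesis had 4 of 25 lower and 1 higher (6 and 3 adjusted over the list alone, 0.0358), with adjusted p = 0.242 with an estimated correlation.

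**Figure D3:**
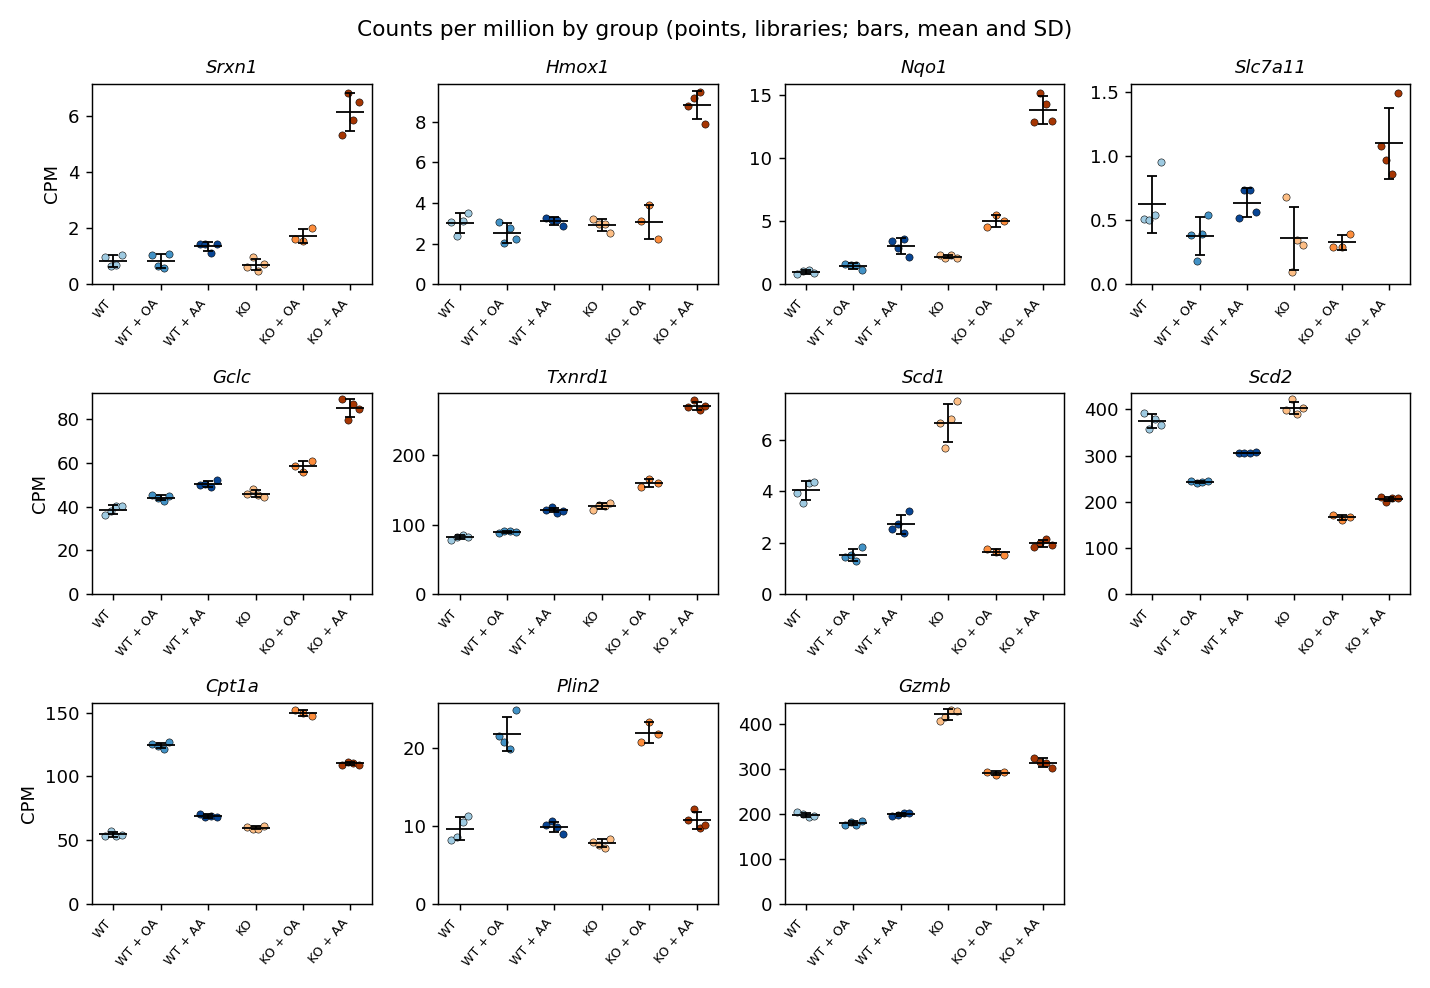
CPM (TMM-scaled) of 11 genes in the 6 groups; points are libraries, bars the group mean and SD (n = 4, and 3 for KO with OA). Srxn1 averaged 0.694 CPM in untreated KO and 6.13 CPM in KO with AA.

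What AA does in KO T cells was asked next. Antioxidant genes were much higher in KO with AA than in untreated KO, and lipid synthesis, cell cycle and effector genes were lower. Srxn1, the sulfiredoxin that repairs peroxiredoxins, was 8.85-fold higher with AA (6.13 ± 0.673 against 0.694 ± 0.200 CPM, SD, n = 4 each, edgeR adjusted p = 6.64e-16). Nqo1 was 6.33-fold higher (13.9 ± 1.13 against 2.19 ± 0.132 CPM, 6.42e-19), and Hmox1, the haem oxygenase, 3.01-fold (8.81 ± 0.689 against 2.93 ± 0.289 CPM, 5.01e-12). Slc7a11 was 3.10-fold higher at a low level (1.10 ± 0.277 against 0.357 ± 0.242 CPM, 2.07e-04) and its partner Slc3a2 1.72-fold. Txnrd1 was 2.14-fold and Gclc 1.85-fold higher. The ferritin genes Ftl1 and Fth1, which store iron, rose 1.82-fold and 1.36-fold. Plaur, the urokinase receptor, rose by 1.47 on the log2 scale and Arrdc3 by 1.43. Scd1, Fads2 and Scd2 fell by 1.75, 1.13 and 0.97, and Itih5, a matrix protein, by 1.11. Gzmb was 1.34-fold lower (315 ± 9.77 against 422 ± 11.9 CPM, edgeR adjusted p = 3.41e-13), and the effector transcription factor genes Eomes and Tbx21 fell by 0.58 each on the log2 scale. Acsl4 was 1.13-fold lower (2.06e-04), and Gpx4 1.12-fold lower (0.00663), a call lost without KO replicate 3 (0.0704). The test called 2201 genes higher and 2772 lower with AA in KO, of which 183 differed at least 2-fold.

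The lists of the AA response in KO were led by NRF2 targets, with 15 of 23 members higher and 1 lower (16 and 3 adjusted over the list alone, median log2 change 0.47, camera adjusted p = 9.76e-34). Cholesterol synthesis had 21 of 25 lower and 1 higher (21 and 1 adjusted over the list alone, 8.84e-26), with the sterol enzyme genes Idi1 and Hmgcs1 down 1.68-fold and 1.60-fold. Cell cycle genes had 24 of 30 lower (25 adjusted over the list alone, 2.87e-17), fatty acid synthesis 12 of 17 lower and 1 higher (12 and 1 adjusted over the list alone, 1.13e-16) and glycolysis 18 of 26 lower and 1 higher (18 and 1 adjusted over the list alone, 3.32e-08), with Hk2, the entry enzyme of glycolysis, down 1.64-fold. LXR targets had 7 of 11 lower and 1 higher (7 and 1 adjusted over the list alone, 6.85e-08). CD8 effector genes had 10 of 26 lower and 1 higher (10 and 1 adjusted over the list alone, 0.00106), and inhibitory receptors and exhaustion genes 12 of 19 lower and 1 higher (14 and 1 adjusted over the list alone, 0.00174). For ferroptosis defence 11 of 27 members were higher and 8 lower (11 and 9 adjusted over the list alone), and the median log2 change of -0.07 had the opposite sign to the mean of 0.11 and to the camera call, which was up (0.00128). Its higher members Gclc, Txnrd1 and Ftl1 are in the NRF2 list too. NK cell markers had 2 of 5 lower (2 adjusted over the list alone, 0.00374). These 2 were Il2rb and Eomes, and Eomes is also in the CD8 effector list. Gzma (edgeR adjusted p = 0.816), Klrb1c (0.28) and Klre1 (0.367) did not pass. The 10 list calls given so far held with an estimated correlation. Oxidative phosphorylation had 19 of 42 lower and 2 higher (21 and 2 adjusted over the list alone, 5.13e-05), with adjusted p = 0.204 with an estimated correlation. Immediate early genes had 9 of 16 lower (9 adjusted over the list alone, 0.00238), with adjusted p = 0.0812 with an estimated correlation. Markers of megakaryocytes and platelets (camera adjusted p = 0.131), plasma cells (0.507) and macrophages and monocytes (0.911) did not pass as lists. Single members of these lists and Slc40a1 were still higher with AA in KO, all named after their values were seen. They were Itga2b (5.31 ± 0.752 against 3.43 ± 0.382 CPM, SD, n = 4 each, edgeR adjusted p = 3.11e-05), Pf4 (log2 0.92, 0.0052), Igha, an immunoglobulin constant gene (log2 1.22, 0.00908), and Slc40a1, the iron exporter (log2 1.66, 0.00282). Pf4 (0.712 ± 0.0658 against 0.378 ± 0.135 CPM), Igha (0.413 ± 0.0866 against 0.178 ± 0.0731 CPM) and Slc40a1 (0.330 ± 0.0962 against 0.102 ± 0.0415 CPM) were near the floor in both groups. None of Itga2b, Pf4, Igha and Slc40a1 passed with AA in WT (0.673, 0.864, 0.983 and 0.917), and in the test of the difference between genotypes only Itga2b passed (0.0378).

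The effect of OA in KO T cells was asked in the same way. Fatty acid oxidation genes were higher in KO with OA than in untreated KO, and lipid synthesis, cell cycle and inhibitory receptor genes were mostly lower. Dtx1 was 4.72-fold higher (8.99 ± 0.0927, n = 3, against 1.91 ± 0.218 CPM, n = 4, SD, edgeR adjusted p = 3.41e-17), and its relative Dtx4 3.45-fold higher. Plin2 was 2.84-fold and Cpt1a 2.50-fold higher (149.6 ± 2.66 against 59.9 ± 1.14 CPM, 1.81e-26), and Bzrap1, a scaffold protein gene, and Nqo1 were 2.40-fold and 2.31-fold higher. Scd1, Fads2 and Scd2 fell by 2.02, 1.52 and 1.28 on the log2 scale, Ptpn5, a phosphatase, by 1.48, Gucy1a3, a cyclase subunit, by 1.41 and Podnl1, a matrix protein, by 1.26. Gzmb was 1.45-fold lower (1.70e-14), and Pdcd1 1.26-fold lower (10.1 ± 0.596 against 12.8 ± 0.417 CPM, 4.93e-04). Il7r was 1.73-fold lower. Acsl4 was 1.14-fold lower (6.08e-04), and Gpx4 1.13-fold lower (0.0104), a call lost without KO replicate 3 (0.0753) or KO with OA replicate 2 (0.112). Hmox1 (edgeR adjusted p = 0.782) and Slc7a11 (0.887) did not pass with OA. The test called 1887 genes higher and 2296 lower, of which 199 differed at least 2-fold.

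For OA in KO, fatty acid synthesis had 10 of 17 members lower (11 adjusted over the list alone, camera adjusted p = 7.64e-18), and cholesterol synthesis 18 of 25 lower and 1 higher (19 and 2 adjusted over the list alone, 2.78e-16). LXR targets had 7 of 11 lower (8 adjusted over the list alone, 9.07e-16), among them Abca1, down 1.68-fold. Fatty acid oxidation had 8 of 28 higher and 3 lower (8 and 3 adjusted over the list alone, 1.47e-06). Cell cycle genes had 17 of 30 lower (17 adjusted over the list alone, 2.79e-05), inhibitory receptors 12 of 19 lower and 2 higher (13 and 2 adjusted over the list alone, 4.45e-04) with Havcr2, the receptor TIM-3, down 1.74-fold. Naive and memory genes had 9 of 20 lower and 3 higher (10 and 3 adjusted over the list alone, 7.25e-04) and CD8 effector genes 7 of 26 lower and 3 higher (7 and 3 adjusted over the list alone, 8.11e-04). For p53 genes 8 of 21 were lower and 1 higher (11 and 1 adjusted over the list alone, 0.00136), and for the integrated stress response 14 of 30 were lower and 3 higher (14 and 4 adjusted over the list alone, 0.00924). These 10 held with an estimated correlation. Glycolysis, with 14 of 26 lower and 1 higher (14 and 1 adjusted over the list alone, 2.01e-04), had adjusted p = 0.0797 with an estimated correlation. CD8 T cell markers had 7 of 12 lower (7 adjusted over the list alone), with adjusted p = 0.126 with an estimated correlation. NRF2 targets had 9 of 23 higher and 3 lower (9 and 3 adjusted over the list alone, 0.00666), with adjusted p = 0.116 with an estimated correlation. NK cell markers (adjusted p = 0.0616 with an estimated correlation) and dendritic cell markers (adjusted p = 0.0843 with an estimated correlation) were lower at the preset value alone. Markers of megakaryocytes and platelets (camera adjusted p = 0.413), plasma cells (0.966) and macrophages and monocytes (0.447) did not pass with OA either. Of the genes named for AA after their values were seen, Itga2b (log2 0.60, edgeR adjusted p = 2.21e-04) and Slc40a1 (log2 1.35, 0.0352) were also higher with OA in KO. Slc40a1 was near the floor there too (0.266 ± 0.0246 CPM with OA), and Pf4 (0.198) and Igha (0.127) did not pass. For the difference of the OA effect between genotypes only Slc40a1 passed (0.0346).

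**Figure D4:**
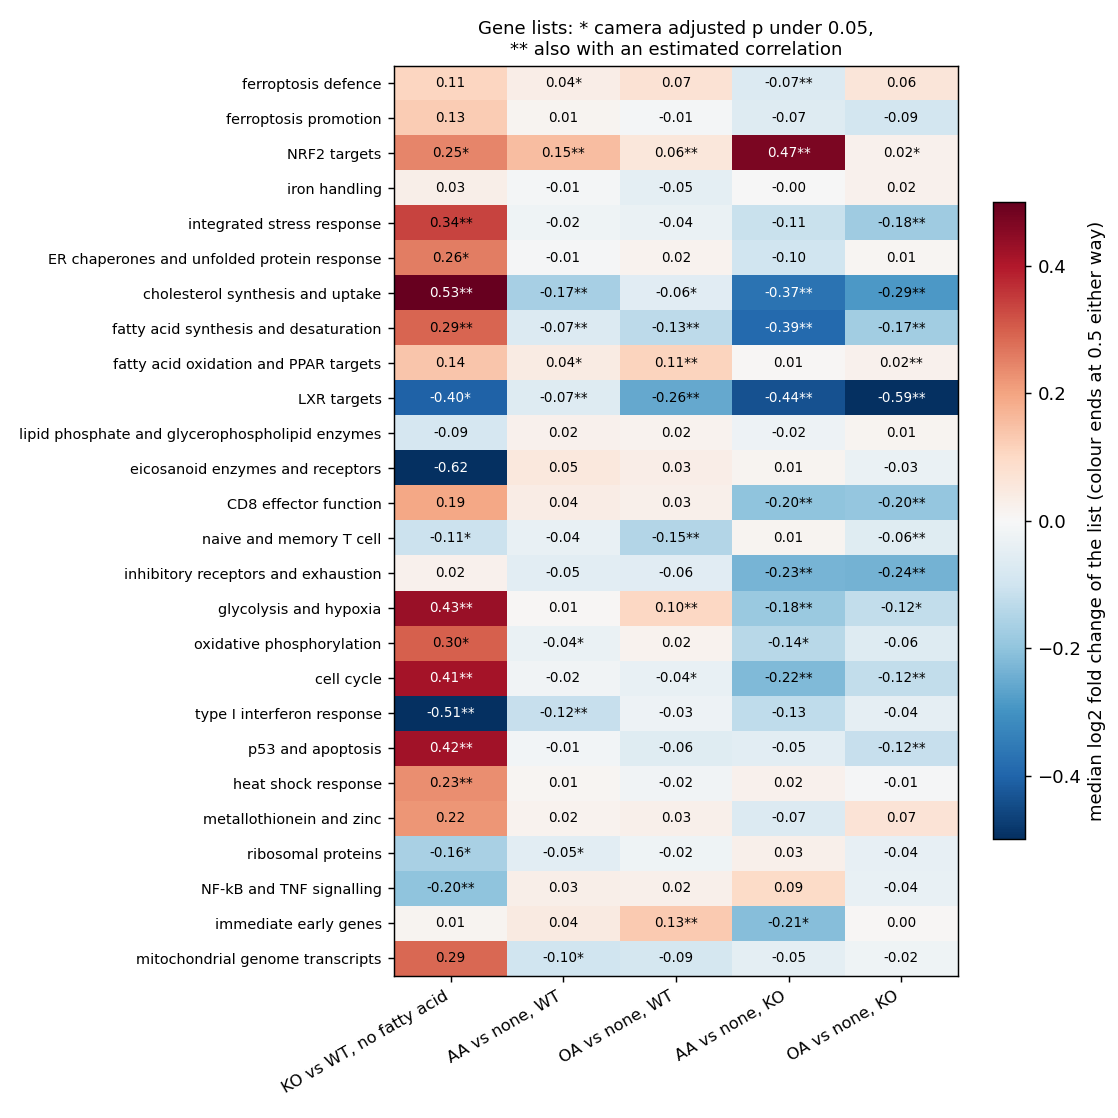
Median log2 fold change of each gene list, cell type markers left out, in 5 comparisons; 1 star marks a camera adjusted p under 0.05 and 2 stars a call that also held with an estimated correlation. NRF2 targets had medians of 0.15 with AA in WT and 0.47 with AA in KO.

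Whether the AA response differs between genotypes was tested on the difference itself. Srxn1 rose by 2.44 more on the log2 scale in KO than in WT (SE 0.277, edgeR adjusted p = 8.57e-08), Hmox1 by 1.53 more, Plaur by 1.34 more (SE 0.095) and Nqo1 by 1.03 more (SE 0.199). Cpt1a rose by 0.54 more (8.42e-11), Fth1 by 0.33 more and Plin2 by 0.43 more. Slc7a11 rose by 1.60 more (0.0159), a call lost without WT replicate 4 (0.0571). Lower in KO relative to WT were the effects on Scd1 (log2 -1.19), Srm, a polyamine enzyme (-1.13), Egr3, an early response gene (-0.96), Scd2 (-0.68) and Tfrc (-0.38). Gzmb differed by -0.43 (SE 0.044). The difference was past the threshold for 2513 genes, 1075 of them higher and 1438 lower in KO, and with upper quartile factors 52.7% of the called genes were higher, against 42.8% with TMM. NRF2 targets had 11 of 23 members with a higher effect in KO and 1 with a lower one (12 and 2 adjusted over the list alone, median log2 difference 0.33, camera adjusted p = 1.14e-13). Cell cycle genes had 21 of 30 lower (22 adjusted over the list alone, 5.16e-15), glycolysis 12 of 26 lower (14 adjusted over the list alone, 6.69e-10) and fatty acid synthesis 7 of 17 lower (7 adjusted over the list alone, 1.04e-08). CD8 effector genes had 6 of 26 lower (9 lower and 1 higher adjusted over the list alone, 1.12e-04). All 5 held with an estimated correlation, and 13 lists passed in total, 9 of them with an estimated correlation. Ferroptosis defence did not pass (0.0737). The cell cycle list's median log2 difference between KO and WT was 0.41 without fatty acid and 0.24 with AA. Pdcd1 differed by -0.30 (edgeR adjusted p = 0.0239), a call lost without WT with AA replicate 1 (0.0689) or 4 (0.0542), KO with AA replicate 4 (0.07) or WT replicate 1 (0.0548) or 2 (0.0538).

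Whether the OA response differs between genotypes was tested likewise. The difference was past the threshold for 2256 genes, of which 1063 were higher and 1193 lower in KO. Dtx4 and Dtx1 rose by 1.25 and 1.18 more on the log2 scale in KO (edgeR adjusted p = 4.06e-09 and 4.36e-07), Ccr9, a gut homing receptor, by 1.08 more and Pmepa1, an inhibitor of TGF-beta signalling, by 0.94 more. Tex15, a germ cell gene, differed by -1.15, Aldoc, a glycolytic aldolase, by -1.12 (SE 0.265), Adap1, a GTPase-activating protein, by -0.97 and Fosb by -0.92. Scd2 differed by -0.66, Abca1 by -0.63, Gzmb by -0.40 and Pdcd1 by -0.36 (0.01). Scd1 differed by -0.62 (0.0233), a call lost without WT replicate 2 (0.056), WT with OA replicate 4 (0.0933), KO replicate 4 (0.0529) or KO with OA replicate 2 (0.0563) or 3 (0.0676). Cpt1a differed by 0.14 (0.0443), and its call was lost with the replicate block (0.0654) and without any of 8 libraries, such as WT replicate 2 (0.132). With upper quartile factors 57.7% of the called genes were higher in KO, against 47.1% with TMM. Glycolysis genes had 14 of 26 with a lower effect in KO (15 adjusted over the list alone, camera adjusted p = 4.71e-12) and cholesterol synthesis 15 of 25 (16 adjusted over the list alone, 8.31e-11). Fatty acid synthesis had 7 of 17 (9 adjusted over the list alone, 2.15e-05), LXR targets 5 of 11 (6 adjusted over the list alone, 2.96e-05) and CD8 effector genes 9 of 26 lower (9 adjusted over the list alone, 1.45e-04). These 5 held with an estimated correlation. NRF2 targets did not differ as a list (camera adjusted p = 0.74), but single members, named after their values were seen, went both ways. Srxn1 (log2 1.28, edgeR adjusted p = 0.00426), Txnrd1 (0.20, 0.00445) and Sqstm1 (0.16, 0.00929) had a higher effect in KO. Tkt (-0.39, 1.18e-05), Pgd (-0.24, 0.00267) and Prdx1 (-0.25, 0.0326) had a lower one.

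The genotypes were also compared with AA present in both. KO T cells had higher antioxidant and cell cycle genes and lower interferon genes than WT T cells. Nqo1 was 4.59-fold and Srxn1 4.52-fold higher in KO (13.9 ± 1.13 against 3.03 ± 0.638 CPM and 6.13 ± 0.673 against 1.35 ± 0.166 CPM, SD, n = 4 each). Arrdc3 was 3.29-fold and Nt5e 3.80-fold higher, and Hmox1 2.83-fold. Gzmb was 1.58-fold higher, while Pdcd1 (edgeR adjusted p = 0.589), Gpx4 (0.942) and Acsl4 (0.520) did not pass. Abca1 fell by 1.30 on the log2 scale, Ikzf2, the transcription factor Helios, by 1.44 and the olfactory receptor gene Olfr524 by 3.21. There were 7693 genes past the threshold, 3867 higher and 3826 lower. NRF2 targets had 21 of 23 higher (21 adjusted over the list alone, camera adjusted p = 3.15e-19), cell cycle genes 26 of 30 higher (27 adjusted over the list alone, 3.30e-09) and interferon genes 16 of 26 lower and 3 higher (16 and 3 adjusted over the list alone, 2.62e-11). Inhibitory receptors had 11 of 19 lower and 2 higher (12 and 2 adjusted over the list alone, 3.20e-04), with Tox, a transcription factor of exhausted T cells, among them. Ferroptosis defence had 11 of 27 higher and 5 lower (11 and 5 adjusted over the list alone, 5.79e-04). These 5 held with an estimated correlation, as did 6 more of the 16 lists called.

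The genotypes were compared with OA present in both as well, and Nt5e was 4.39-fold higher in KO (20.9 ± 0.957, n = 3, against 4.74 ± 0.338 CPM, n = 4, SD), Drc1 3.66-fold, Nqo1 3.47-fold and Cdkn1a 2.94-fold. Mme fell by 7.44 on the log2 scale and Magi1 by 5.28. Gzmb was 1.62-fold and Tfrc 1.71-fold higher, and Pdcd1 (edgeR adjusted p = 0.205), Gpx4 (0.660) and Acsl4 (0.316) did not pass. There were 7763 genes past the threshold, 3905 higher and 3858 lower. Cell cycle genes had 28 of 30 higher (28 adjusted over the list alone, camera adjusted p = 3.32e-18), interferon genes 18 of 26 lower and 1 higher (18 and 1 adjusted over the list alone, 1.72e-11), and NF-kB genes such as Relb and Nfkb2 13 of 21 lower and 2 higher (14 and 2 adjusted over the list alone, 1.50e-04). NRF2 targets had 17 of 23 higher and 1 lower (17 and 1 adjusted over the list alone, 2.73e-05). These 4 held with an estimated correlation, as did 7 more of the 16 lists called.

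Whether AA and OA act differently was asked in each genotype. In WT, AA left Plin2 2.20-fold, Dtx1 2.05-fold, Bzrap1 1.78-fold and Cpt1a 1.80-fold below their levels with OA. Nqo1 was 2.07-fold, Scd1 1.78-fold, Eid3 1.80-fold and Olfr524 1.83-fold above them. The test called 351 genes higher and 180 lower with AA, 531 in all, and 349 without WT with OA replicate 4. Fatty acid oxidation had 8 of 28 members lower with AA than with OA (9 lower and 1 higher adjusted over the list alone, camera adjusted p = 3.45e-19). Naive and memory genes, with Il7r and Actn1 among them, had 11 of 20 higher and 1 lower (13 and 1 adjusted over the list alone, 5.94e-16), and cholesterol synthesis had 5 of 25 lower (16 adjusted over the list alone, 1.86e-14). In KO, AA against OA called 1213 genes higher and 1315 lower. Dtx1 was 4.23-fold and the repressor gene Hic1 2.58-fold lower with AA, while Srxn1 was 3.57-fold, Hmox1 2.85-fold and Slc7a11 3.36-fold higher. NRF2 targets had 16 of 23 higher with AA (16 adjusted over the list alone, 2.23e-35), ferroptosis defence 9 of 27 higher and 2 lower (9 and 2 adjusted over the list alone, 1.71e-08) and p53 genes 7 of 21 higher (9 higher and 1 lower adjusted over the list alone, 3.26e-05). Gclc, Txnrd1 and Ftl1, all higher, are in both the NRF2 and the ferroptosis defence list, so these 2 calls are not separate results. Immediate early genes had 10 of 16 lower (12 adjusted over the list alone, 2.86e-08). All 7 lists named for these contrasts held with an estimated correlation.

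The 4 effects of fatty acids overlapped in part. In WT, 10 genes were higher with both AA and OA (0.356 for independent lists) and 34 lower (1.15), and 2 moved in opposite directions. In KO the numbers were 1085 (231), 1475 (353) and 56. Across the 18015 genes, which are not independent replicates, the AA and OA effects correlated at r = 0.48 in WT and 0.59 in KO, but both effects share the same untreated libraries, and simulated unchanged groups gave 0.50 and 0.48. Their covariance exceeded the simulated one by 0.00761 in WT and by 0.0426 in KO. With the untreated libraries split between the effects, the mean correlation was 0.04 in WT (-0.02 to 0.05 over 6 splits) and 0.27 in KO (0.26 to 0.29). Between genotypes, which share no libraries, the effects of AA correlated across genes at r = 0.11 (rho = 0.13) and those of OA at r = 0.18 (rho = 0.15). For AA, 26 genes were higher in both genotypes (3.54 for independent lists) and 38 lower (7.08), with 2 opposite. For OA, 119 were higher (23.1), 284 lower (57.5) and 48 opposite. The median absolute log2 change of the 75 genes called with AA in WT was 0.23 there and 0.52 in KO, and for the 672 OA genes it was 0.24 and 0.25.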

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

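In this part the tests of KO replicate 4, of scaling, of genotype, receptor and sex and of the untreated KO libraries were chosen after related results were seen, and the 11 counts over other splits of the libraries and the test of the genes near Plpp1 were chosen before.

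A library far from the others of its group was found in 12 of 185 groups of values, where chance gives about 1 in 20, or 9.25. The share of Trav14 was 79.0% in WT replicate 4 (78.0 to 78.1% in the others) and 11.3% in KO with AA replicate 2 (11.5 to 11.6%). Trac stood at 264.9 CPM in WT with AA replicate 3 (249 to 251 CPM), Xist at 810.0 CPM in WT with OA replicate 4 (866 to 874 CPM) and total Trav at 136 CPM in WT with AA replicate 2 (146 to 148 CPM). A set of 12 repeat-type predicted genes stood at 162 CPM in WT with OA replicate 1 (23.3 to 38.5 CPM) and at 384 CPM in KO replicate 4 (7.39 to 19.5 CPM). The mitochondrial share was 2.32% in KO with AA replicate 1 (1.67 to 1.76%), and the total count was 58.9 M in KO with AA replicate 2 (48.3 to 48.8 M), which is 58878203 counts. Slc7a11 stood at 0.954 CPM in WT replicate 4 (0.499 to 0.538 CPM), Fth1 at 107 CPM in WT with OA replicate 4 (99.1 to 99.6 CPM) and Tfrc at 137 CPM in WT with OA replicate 1 (131.7 to 132.5 CPM).

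The AA effect differed between genotypes for 2513 genes by the test of the difference. Named genes with a larger or more positive effect in KO, on the log2 scale, were Srxn1 (2.44), Slc7a11 (1.60), Hmox1 (1.53), Plaur (1.34), Lrrc8dos (1.05), Nqo1 (1.03), Cpt1a (0.54), Plin2 (0.43) and Fth1 (0.33). Those with a lower one were Scd1 (-1.19), Srm (-1.13), Egr3 (-0.96), Bspry (-0.96), Scd2 (-0.68), Gzmb (-0.43), Abca1 (-0.42), Tfrc (-0.38), Pdcd1 (-0.30) and Acsl4 (-0.19). Among lists, the median difference was 0.33 for NRF2 targets and 0.076 for ribosomal proteins. It was -0.33 for NK cell markers, -0.28 for immediate early genes, -0.24 for LXR targets, -0.23 for CD8 effector genes and -0.23 for glycolysis. It was -0.20 for cell cycle and for fatty acid synthesis, -0.19 for cholesterol synthesis, -0.18 for inhibitory receptors, -0.10 for oxidative phosphorylation and -0.082 for chaperones of the endoplasmic reticulum. The chaperone call (camera adjusted p = 0.0495) was lost without KO replicate 4 (0.0528) and had adjusted p = 0.293 with an estimated correlation. Oxidative phosphorylation, NK cell markers and ribosomal proteins lost theirs too, with adjusted p = 0.452, 0.0521 and 0.671 with an estimated correlation.

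The OA effect differed for 2256 genes by the same test. Named genes with a more positive effect in KO included Dtx4 (1.25), Dtx1 (1.18), Ccr9 (1.08), Pmepa1 (0.94) and Cpt1a (0.14). Those with a lower one included Tex15 (-1.15), Aldoc (-1.12), Adap1 (-0.97), Fosb (-0.92), Scd2 (-0.66), Abca1 (-0.63), Scd1 (-0.62), Gzmb (-0.40) and Pdcd1 (-0.36). The lists' median differences were -0.28 for cholesterol synthesis, -0.27 for LXR targets, -0.23 for fatty acid synthesis, -0.22 for CD8 effector genes and -0.21 for glycolysis. Inhibitory receptors (-0.16), CD8 T cell markers (-0.15) and cell cycle (-0.076) lost their calls, with adjusted p = 0.0821, 0.324 and 0.0904 with an estimated correlation.

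Other splits of the libraries were counted for each comparison, and in 9 of the 11 comparisons only 1 of 35 splits, the real one, gave as many genes. The real count and the highest other were 8975 and 0 for KO against WT without fatty acid, 7693 and 170 with AA and 7763 and 4801 with OA. They were 75 and 9 for AA and 672 and 0 for OA in WT, 4973 and 237 for AA and 4183 and 2425 for OA in KO. For AA against OA they were 531 and 0 in WT and 2528 and 1486 in KO. The high other counts with KO and OA came from splits that exchanged 6 of the 7 libraries between groups, which is close to the real split with its sign turned. For the differences between effects, 4 of 100 splits gave as many genes as the real ones, with highest others of 10267 against 2513 for AA and 8870 against 2256 for OA. The others that passed the real count kept or exchanged the genotype labels of all 8 untreated libraries, but not to the same extent those of the treated ones. The genotype difference itself then enters the contrast, a structure of the samples. Splits that mixed both sides, such as 1 with 2 untreated and 6 treated libraries exchanged, gave 0 genes. In these the genotype difference lies within the groups and widens their spread, which by itself leads to few calls. Neither kind of split therefore tests whether the differences between effects exceed chance.

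Weighed first were the many genes that differed between untreated genotypes. Sex chromosome and receptor genes made up 268 and 191 of the 8975 calls, and 49.4% of the other tested genes were called. With only 571 and 222 such genes tested, they could not have made up all calls. This count does not test whether sex or receptor repertoire acts on other genes. A wrong genotype label on a single library was excluded, since 0 libraries lay nearer the other genotype's Trbv12-1 share, but an exchange of whole groups would not show in it. Animals that differ in receptor repertoire and sex cannot be told apart from deletion of Plpp1, because the Trbv12-1 share differed by 80.6 points and ran with genotype, and a transgenic receptor in WT cells may be one reason. A segment of another strain's chromosome was tested for the genes within 10 Mb of Plpp1 alone, where it stayed open with an odds ratio of 0.461 for 2-fold changes (Fisher p = 0.443, 95% interval 0.0547 to 1.74), while 1076 of the 1078 genes with such changes lay elsewhere.

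Weighed next was the larger AA response of NRF2 targets in KO. KO replicate 4 was excluded as its cause, with camera adjusted p = 1.03e-14 without it. Scaling was excluded, with a lowest median difference of 0.34 under other factors. Untreated KO libraries that stand apart were excluded as the whole cause, since the list's difference of AA from OA, which uses no untreated library, was larger in KO than in WT (camera adjusted p = 3.71e-20). Deletion of Plpp1 as the cause is a hypothesis that stayed open, since its median difference of 0.33 cannot be told apart from an effect of repertoire, activation state or sex.

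Weighed last were the glycolysis, cell cycle and CD8 effector lists, lower with both fatty acids in KO, although glycolysis with OA had adjusted p = 0.0797 with an estimated correlation. KO replicate 4 was excluded as the cause, with a largest camera adjusted p of 0.00295 without it. Untreated KO libraries that stand apart from all treated ones cannot be told apart from an effect of both fatty acids, since AA and OA differed by at most 0.13 in the median of these lists.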

How the results depend on the processing

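No named gene changed direction under any alternative. No list did under those it was tested with, which were an estimated correlation, fry, the replicate block and leaving out KO replicate 4. With upper quartile factors the share of called genes higher in KO went from 42.8 to 52.7% for the AA difference and from 47.1 to 57.7% for the OA difference, so the side with more genes turned. Counts of changed genes stayed within 1.5 times the reported count, except for AA in WT with DESeq2 (137, sharing all 75) and without WT replicate 1 (48), OA in WT without WT replicate 2 (436) and AA against OA in WT without WT with OA replicate 4 (349), and the cause was not tested. With each library left out in turn, the count ran from 8377 to 8603 for KO against WT without fatty acid, 7123 to 7347 with AA and 6837 to 7379 with OA. It ran from 48 to 73 for AA and 436 to 642 for OA in WT, 4341 to 4702 for AA and 3189 to 4040 for OA in KO, 349 to 412 for AA against OA in WT and 1698 to 2600 in KO, and 2118 to 2548 and 1618 to 2367 for the differences of the AA and OA effects. With the replicate block the counts were 8889, 7576, 7518, 59, 595, 4829, 3915, 470, 2299, 2353 and 1972 in the same order. The block ended the calls of the chaperone list for the AA difference (0.058), Acadvl (0.0538), Ftl1 (0.0677) and Srebf1 (0.0538) with AA in WT, Ccne1 (0.0777) and Myc (0.0601) with OA in WT, Tcf7 with AA in KO (0.0529) and Cpt1a for the OA difference (0.0654), and made new ones for Slc7a11 (0.0493) and the mitochondrial genome list (0.0491) in untreated KO and for CD4 T cell markers between genotypes with AA (0.0487). It changed no other call of a named gene or list. Over 55 same-number pairs the mean correlation was 0.004, with 1 over 0.1, and 6 of 23 libraries matched their own number best. Taken over all groups, the numbers therefore did not pair the samples. On the second axis of a principal component analysis, untreated WT replicates 1 to 4 stood at 10.7, 7.30, -8.18 and 0.597. Those of WT with AA stood in the same order, at 13.4, 7.62, -8.50 and -4.37. WT with OA, untreated KO and KO with AA had other orders. A factor shared by number between untreated WT and WT with AA is not excluded. Of 142 list calls, 47 were lost with an estimated correlation and 8 with fry. Of 756 calls or non-calls of named genes, 11 calls were lost without a filter, 8 of 753 with only the groups compared, 7 with upper quartile factors, 7 with the block and 2 each with voom, RLE factors and the stricter filter (of 637). New calls numbered 3 with DESeq2 (of 741, none lost), 3 with voom, 2 each without and with a stricter filter and 1 each with upper quartile factors and the block. Leaving out libraries ended calls of named genes in 188 of 6743 fits and made 12. Halved counts and the lists without KO replicate 4 were chosen after seeing the data. Halved counts changed the call of 1 named gene of 756, and depth limits genes near the floor such as Plpp1, at 15 to 39 counts per library.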

Other observations

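The genotypes also differed in genes not described so far. Ifng, the main T cell interferon, was 0.422 ± 0.124 CPM in untreated KO and 0.102 ± 0.118 CPM in untreated WT (SD, n = 4 each, log2 2.14, edgeR adjusted p = 0.001). Ifng was near the floor in both groups. Within 10 Mb of Plpp1, 2 of 70 tested genes differed at least 2-fold between untreated genotypes, against 1076 of 17945 elsewhere. They were Gzma, a granzyme (log2 -2.43), and Itga1, an integrin of resident memory T cells (log2 1.94), both named after their values were seen.

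In this part the test of single animals was chosen after the receptor and sex values were seen. Both Xist above 100 CPM and Ddx3y above 10 CPM were present in 12 of 12 WT libraries, which excludes that each came from a single animal of 1 sex, so they may hold cells pooled from female and male mice. Their levels were alike in all 12, with Xist from 804 to 907 CPM and Ddx3y from 58.1 to 65.6 CPM. Whether the libraries share 1 pool is not in the labels, so they may not be separate biological replicates.

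Trbv29 and Trbv16 made up 15.1 ± 0.907% and 14.8 ± 1.05% of the Trbv counts in KO, against 2.36% and 2.53% in WT. Total Trbv counts were 196 ± 8.91 CPM in WT and 199 ± 14.7 CPM in KO. Hemoglobin transcripts stood at 0.592 ± 0.166 CPM in WT and 0.288 ± 0.152 CPM in KO, and mitochondrial transcripts made up 1.64 ± 0.0762% and 1.88 ± 0.186% of the counts.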
